A study of Mus musculus with 43 samples.

How the data were processed

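The data are bulk RNA-seq of mouse whole hearts, endothelial cells and cardiomyocytes that are wild type or carry the Q150X stop codon in Vegfa, at homeostasis and after MI. The labels name Trizol extraction and 2 µg of RNA per library. Strain, sex and the origin of the replicates are not given in the sources used here. The deposited table holds raw counts for 57010 genes in 43 libraries of 14 groups. Per the submitters' processing notes the genome build is GRCm39 and HISAT2 and kallisto were used. Their versions, which of them made the counts, the annotation and the strandedness are not given in the sources used here. All values are whole numbers, each of the 43 columns names 1 sample, and none of the 47 replicate pairs is identical. Single-nucleus data of the series were not analysed.

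Gene symbols came from GENCODE vM21, an annotation of the earlier build GRCm38, by gene identifier. They were found for 52029 identifiers, and the 4981 without one held at most 0.18% of the counts of a library. The 20544 genes with 0 counts in all libraries were left out. Total counts per library were 25948706 to 37356177 in hearts, 32008175 to 45243608 in endothelial cells and 25035490 to 42246348 in cardiomyocytes. The squared difference between replicates, in units of counting noise, was 8.45 to 1193 per gene, so the spread between samples exceeds that of counting.

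Each compartment was fitted alone with edgeR 4.0.16 in R 4.3.3 (TMM factors, robust quasi-likelihood F-test, 1 mean per group), after a filter by group (filterByExpr, count minimum 10 and total minimum 15) that kept 17845 genes in hearts, 18223 in endothelial cells and 15169 in cardiomyocytes. The 15 comparisons are 7 of Q150X with wild type, 4 of MI with homeostasis in wild type, and 4 interactions. A gene changed if its p, adjusted by Benjamini and Hochberg over the genes of the compartment, was under 0.05. The SE is the log2 fold change over the root of F. For levels, CPM uses TMM-scaled library sizes. With 1 to 3 counts in a group, pooled ratios with a counting interval are given.

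The 27 gene lists were written before the data were examined, as were groups, comparisons, tests, thresholds and the first set of alternatives. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. By a rule set then, genes named in genotype comparisons are Vegfa, Kdr and Flt1, the 10 largest called changes per direction, up to 4 members with the smallest p in each called list, and the 3 smallest p per direction where fewer than 5 genes passed. MI comparisons name 6 per direction and interactions the 5 smallest p per direction, of which up to 3 are given. Of the genes so named, 2 are not reported here. Lists whose call was lost without 1 library are partly given as a count or median alone, a choice made after the data were examined.

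The fits were tested on simulated counts with 200 changed genes per comparison, and for 2-fold and 4-fold changes the percentages recovered were 39 and 73 for the genotype in hearts at homeostasis, 49 and 76 at day 7, 38 and 74 at day 30, and 0 and 14 in endothelial cells at day 3. A list raised in the simulation was recovered in all 3 compartments with 0 false lists. This does not test the real list calls.

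Alternatives planned before the data were examined were size factors of DESeq2 in edgeR, library size without a composition factor, no filter on low counts, a fit of the compared groups alone, replicate number as a block, DESeq2 1.42.0, and leaving out each library in turn. Added later were voom with library weights (limma), leaving out libraries that stand apart in their marker genes (4 in all, none in cardiomyocytes), and a block at homeostasis only. Same-numbered libraries deviate together in hearts at homeostasis (r = 0.31 to 0.59 in 3 pairs), where the pairing comes from the data, and at no other time point do all pairs exceed 0.1. Samples, save endothelial cells at day 3, were also split into all other groupings of the same sizes, or 50 drawn ones for interactions. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.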

Results

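The 43 bulk RNA libraries come from mice that are wild type or carry a CRISPR-edited stop codon in Vegfa (Q150X), the gene of the main growth factor of blood vessels. Whole hearts were sampled without injury (homeostasis) and 7 and 30 days after myocardial infarction (MI), and endothelial cells and cardiomyocytes at homeostasis and 3 days after MI. Each homeostasis group has 3 libraries. Whole hearts have 4 libraries of each genotype at day 7 and 4 Q150X and 3 wild-type libraries at day 30. Endothelial cells have 2 and cardiomyocytes 3 of each genotype at day 3. Libraries held 25035490 to 45243608 counts. Values of single genes are log2 fold changes ± standard error (SE) from edgeR, with p adjusted over all genes tested in the compartment. Genes picked by size or smallest p have a mean of at least 1 log2 CPM and no name of a numbered Gm or Rik transcript, pseudogene or bare identifier, so other genes can have a larger change or smaller p. Those picked by size also have no overlap of the groups. Levels are CPM (counts scaled to library size), mean ± SD. Gene lists were tested with camera at a preset correlation of 0.01 between genes. They are given with the median log2 fold change of their genes and the adjusted p. Estimated-correlation p is the adjusted p of camera with an estimated correlation. Labels do not say if replicates are separate animals, so p and SE measure sample spread over a whole compartment.

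Vegfa mRNA was detected in both genotypes in all 7 genotype comparisons, and none of the differences passed the test. In whole hearts Vegfa stood at 418 ± 242 CPM in Q150X and 463 ± 252 in wild type at homeostasis (-0.15 ± 0.39). The means were 311 ± 16.1 and 291 ± 45.1 at day 7 (0.10 ± 0.34) and 228 ± 38.5 and 201 ± 33.1 at day 30 (0.18 ± 0.37). Endothelial cells had 108 ± 13.7 and 102 ± 3.07 CPM at homeostasis (0.09 ± 0.49) and 98.2 ± 97.3 and 141 ± 5.06 at day 3 (-0.53 ± 0.60). Cardiomyocytes had the highest levels of the sorted fractions, 525 ± 86.7 and 502 ± 49.5 CPM at homeostasis (0.06 ± 0.15) and 290 ± 64.8 and 299 ± 36.04 at day 3 (-0.05 ± 0.15). Every library held between 1231 and 18493 Vegfa counts. A count per gene does not show the stop codon, so these levels do not check the genotype labels. Adjusted p was between 0.862 and 1 for Vegfa, except for 0.613 in endothelial cells at day 3. There the Q150X libraries differ from each other (167 and 29.4 CPM): without number 1 the Vegfa difference is -2.30 and passes the test, and without number 2 it is 0.21.

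The main VEGF receptors of endothelium gave no called difference either, though the values of both lie below 0 in all 7 comparisons. Kdr differed by -0.27 ± 0.31, -0.12 ± 0.27 and -0.10 ± 0.29 in whole hearts at homeostasis, day 7 and day 30. Flt1 differed by -0.29 ± 0.29, -0.32 ± 0.25 and -0.48 ± 0.27. In endothelial cells Kdr differed by -0.26 ± 0.53 at homeostasis and -1.50 ± 0.67 at day 3, and Flt1 by -0.00 ± 0.55 and -1.12 ± 0.68. In cardiomyocytes, where endothelial transcripts are a minor part, the values were -0.78 ± 0.31 and -0.06 ± 0.30 for Kdr and -0.79 ± 0.36 and -0.01 ± 0.36 for Flt1.

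**Figure D1:**
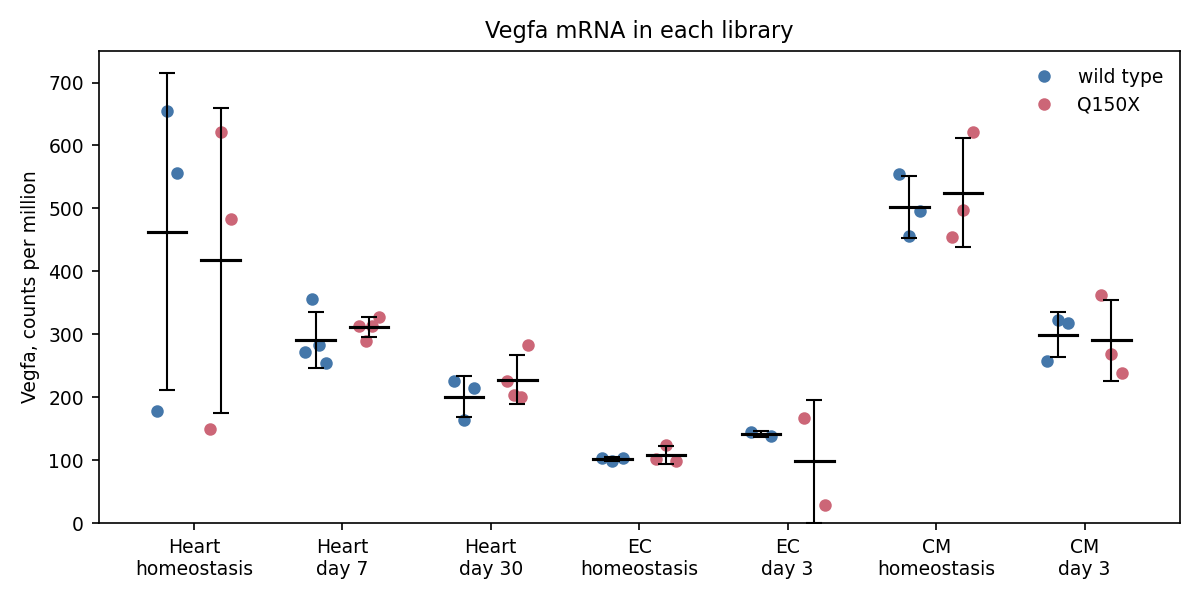
Vegfa in CPM (vertical axis) for each of the 43 libraries, by group and genotype; points are libraries, horizontal bars group means and vertical bars the SD. The ranges of the genotypes overlap in every group, and whole hearts at homeostasis span 150 to 655 CPM.

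The fractions carried the markers of their labels, except Q150X endothelial library 2 of day 3 (endothelial identity 5.73, under the whole-heart median). The median of 22 genes of endothelial identity was 9.39 log2 CPM in the middle endothelial library, 6.13 in whole heart and 3.36 in cardiomyocytes. The 20 genes of cardiomyocyte structure stood at 5.15, 11.1 and 11.3. Some libraries stood apart. The Q150X endothelial library 2 of day 3 held 1290 CPM of Rag1 against at most 1.22 in the other 9 endothelial libraries. It held 330 CPM of the endothelial adhesion gene Pecam1 against 1060 to 1616 in the other libraries of that day. All 4 endothelial libraries of day 3 also held leukocyte Ptprc (at least 237 CPM). They had Xist (494 to 1089 CPM), RNA of the inactive X, and hardly any Y-linked Ddx3y (at most 0.501). The 6 of homeostasis had Ddx3y at 188 to 267 CPM and Xist at most 1.19. Whole-heart homeostasis libraries number 1 of both genotypes held the atrial light chain Myl7 (525 and 468 CPM against at most 0.0336 in the other homeostasis hearts) and the fat hormone Adipoq (11.2 and 8.96 against at most 0.317). The wild-type heart library 4 of day 7 held the placental gene Tpbpa at 467 CPM.

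At 7 days after MI in wild-type hearts (n = 4 against 3 at homeostasis), matrix genes such as Lox and Postn rose. The matrix list ranked higher by camera at the preset correlation alone, and most of its genes did not pass. Lox (4.29 ± 0.46, 115 ± 39.4 against 5.88 ± 2.13 CPM, adjusted p = 1.6e-05), Postn (3.26 ± 0.50), Tnc (3.79 ± 0.69) and Cthrc1 (7.26 ± 1.01) rose. So did osteopontin Spp1 (5.03 ± 0.92) and Serpina3n (4.07 ± 0.82). The predicted transcript AC160336.1 (3.63 ± 0.62) is the remaining one of the 6 largest rises. The 6 largest falls were Itgb6 (-3.89 ± 0.34, adjusted p = 2.4e-06), Apln (-3.36 ± 0.61), Rtn4r (-3.27 ± 0.55), Tuba4a (-3.08 ± 0.26), Klhdc8a (-2.85 ± 0.34) and Lingo3 (-2.83 ± 0.39). Among genes of the fatty acid oxidation list, Pdk4 (3.11 ± 0.49), which curbs the oxidation of pyruvate, rose. In all, 2448 of 17845 genes changed, 1365 upward and 1083 downward.

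By list, genes of fibroblasts and extracellular matrix ranked higher at day 7 (median 0.71, adjusted p = 9.6e-06, estimated-correlation p = 0.798, 9 rose, 1 fell, 23 of 33 did not pass, 13 rose and 1 fell adjusted over the list alone). So did monocyte and macrophage genes (median 0.72, adjusted p = 0.00212, estimated-correlation p = 0.798, 7 rose, 1 fell, 14 of 22 did not pass, 9 rose and 1 fell adjusted over the list alone), among them Gpnmb (2.74 ± 0.60). Angiogenic sprouting ranked lower (median -0.49, adjusted p = 5.2e-04, estimated-correlation p = 0.798, 1 rose, 6 fell, 17 of 24 did not pass, 1 rose and 9 fell adjusted over the list alone), with Unc5b (-1.14 ± 0.26) beside Apln. Nuclear-encoded genes of oxidative phosphorylation ranked lower (median -0.20, adjusted p = 0.00122, estimated-correlation p = 0.798, 2 fell, 44 of 46 did not pass, 1 fell adjusted over the list alone) with Cycs (-0.53 ± 0.14). Fatty acid oxidation ranked higher (median 0.19, adjusted p = 0.00887, estimated-correlation p = 0.798, 4 rose, 20 of 24 did not pass, 5 rose adjusted over the list alone). Cardiomyocyte structure was lower (median -0.24, adjusted p = 0.00887, estimated-correlation p = 0.798, 1 rose, 4 fell, 15 of 20 did not pass, 1 rose and 4 fell adjusted over the list alone). Inflammatory cytokines (median 1.26, adjusted p = 0.0288, estimated-correlation p = 0.798, 2 rose, 16 of 18 did not pass, 3 rose adjusted over the list alone) complete the 7 lists called of 27 tested. The count was 1430 without homeostasis library 3, 1539 without day 7 library 4, which holds placental RNA markers, and 5896 with voom. Unc5b lost its call without homeostasis library 1 (adjusted p = 0.0567) and Cycs without library 2 (0.0603). Of the lists, fatty acid oxidation (0.07) and cytokines (1.42) lost theirs without homeostasis library 1, cardiomyocyte structure without library 2 (-0.15) and cytokines without day 7 library 2 (1.27). Cthrc1 lost its call with voom (0.0686). Without the libraries that stand apart Unc5b (0.0722), angiogenic sprouting (-0.27), fatty acid oxidation (0.057) and cytokines (1.26) lost theirs.

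At 30 days after MI, wild-type hearts (n = 3 against 3) had higher values for most genes of the inflammatory and interferon lists. Atrial list medians were 4.003 to 5.24 log2 CPM (2.10 to 2.58 in homeostasis hearts 2 and 3). With Myl7 at most 2.76, Sln 0.23 and Adipoq 18.04 CPM after MI, fat stays open. The largest rises were the chemokines Cxcl10 (8.67 ± 1.78) and Cxcl1 (6.61 ± 1.02) and the selectins Sele (6.90 ± 1.29) and Selp (6.78 ± 1.28). Ptx3 (6.87 ± 0.92, 90.0 ± 98.4 against 0.764 ± 0.637 CPM, adjusted p = 3.0e-04) and Has1 (6.58 ± 0.91) complete the first 6. The largest falls were Tfrc (-1.91 ± 0.31, adjusted p = 0.00116), Atcay (-1.91 ± 0.49), Bvht (-1.88 ± 0.38), Vwa3a (-1.86 ± 0.46), the Notch target Hey1 (-1.83 ± 0.33) and Kctd12b (-1.81 ± 0.38). In all, 1594 of 17845 genes changed, 972 upward and 622 downward.

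Inflammatory cytokines were higher (median 5.30, adjusted p = 3.0e-18, estimated-correlation p = 0.0563, 16 rose, 2 of 18 did not pass, 17 rose adjusted over the list alone). Among them are Il6 (7.14 ± 0.98) and Ccl2 (6.09 ± 0.86). The interferon response was higher (median 2.49, adjusted p = 1.1e-28, estimated-correlation p = 0.0563, 18 rose, 2 of 20 did not pass, 20 rose adjusted over the list alone). It holds the regulator Irf7 (3.51 ± 0.38). Matrix genes ranked higher (median 1.47, adjusted p = 1.2e-14, estimated-correlation p = 0.206, 16 rose, 17 of 33 did not pass, 22 rose adjusted over the list alone) with Postn (2.65 ± 0.50) and Timp1 (4.12 ± 0.83). Macrophage genes did too (median 1.44, adjusted p = 1.3e-09, estimated-correlation p = 0.206, 11 rose, 11 of 22 did not pass, 14 rose adjusted over the list alone), with Cd14 (2.86 ± 0.37). Epicardial genes, with Upk1b (5.28 ± 1.15), were higher (median 4.34, adjusted p = 2.7e-05, estimated-correlation p = 0.206, 4 rose, 4 of 8 did not pass, 6 rose adjusted over the list alone). Neutrophil granule genes were as well (median 3.86, adjusted p = 2.0e-05, estimated-correlation p = 0.206, 5 rose, 5 of 10 did not pass, 8 rose adjusted over the list alone). The immediate early list (median 0.80, adjusted p = 2.4e-05, estimated-correlation p = 0.206, 6 rose, 12 of 18 did not pass, 8 rose adjusted over the list alone) includes Socs3 (4.99 ± 0.63). Lymphatic endothelium (median 1.19, adjusted p = 1.6e-04, estimated-correlation p = 0.206, 3 rose, 1 fell, 4 of 8 did not pass, 6 rose and 1 fell adjusted over the list alone) includes Pdpn (2.50 ± 0.35).

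Fatty acid oxidation was lower (median -0.26, adjusted p = 0.00354, estimated-correlation p = 0.472, 2 fell, 22 of 24 did not pass, 2 fell adjusted over the list alone). Angiogenic sprouting was lower (median -0.26, adjusted p = 0.0382, estimated-correlation p = 0.547, 3 fell, 21 of 24 did not pass, 4 fell adjusted over the list alone), and so was endothelial identity (median -0.31, adjusted p = 0.00380, estimated-correlation p = 0.403, 4 fell, 18 of 22 did not pass, 8 fell adjusted over the list alone). Cardiac stress ranked higher (median 0.30, adjusted p = 0.00919, estimated-correlation p = 0.436, 4 rose, 10 of 14 did not pass, 4 rose adjusted over the list alone). Lymphocytes did too (median 1.57, adjusted p = 0.0101, estimated-correlation p = 0.328, 1 rose, 14 of 15 did not pass, 3 rose adjusted over the list alone). The other 2 of 15 calls among 27 lists, the integrated stress response (0.39, estimated-correlation p 0.328; 0.33 without day 30 library 2) and sex-linked genes (-0.54, 0.340; -0.37 and -0.43 without homeostasis or day 30 library 3), were lost. The rotation test fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 11 of the 15. The count was 457 and 437 without homeostasis libraries 2 and 3, 794 and 502 without day 30 libraries 2 and 3, and 4045 without homeostasis library 1. Without the libraries that stand apart it was 6221 and with DESeq2 2769. Cxcl10 and Upk1b lost their calls without homeostasis library 2 or 3, Atcay without any of these or a day 30 library and Vwa3a without any of them but day 30 library 3 (adjusted p 0.0557 to 0.0956). With voom Cxcl10, Selp and Upk1b lost theirs (0.0618 to 0.182), and Vwa3a did without a filter (0.0541) or with the compared groups alone (0.0525). Without homeostasis library 1, which holds atrial and fat markers, the medians of angiogenic sprouting (-0.08), endothelial identity (-0.09) and cardiac stress (0.56) lost their calls. So did angiogenic sprouting without day 30 library 1 (-0.19) or with library size alone (-0.28), and lymphocytes (1.25) without the libraries that stand apart.

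In wild-type endothelial cells 3 days after MI (n = 2 against 3 at homeostasis), myeloid and inflammatory transcripts were far higher. Leukocytes were not excluded as their source. Arg1 (10.52 ± 1.25, 511 ± 55.3 against 0.346 ± 0.0692 CPM, adjusted p = 0.00246) and the chemokine Cxcl3 (8.92 ± 1.34) rose. The neutrophil genes S100a8 (8.84 ± 1.20), S100a9 (8.02 ± 1.20), Csf3r (7.70 ± 1.14) and Mmp9 (8.17 ± 1.27), and Fpr1 (8.16 ± 1.17) rose. So did Xist (9.26 ± 0.45), and the Y-linked Ddx3y (-9.77 ± 0.44), Eif2s3y (-10.80 ± 0.71), Uty (-10.78 ± 0.70) and Kdm5d (-9.69 ± 0.74) fell. The last 3 had 1 or 2 counts at day 3, and their pooled ratios are 1992-fold (counting interval 551 to 16448), 2159-fold (387 to 85312) and 922-fold (255 to 7616). Expression is female at day 3 and male at homeostasis, so time and sex cannot be told apart. The atrial genes Bmp10 (-6.23 ± 0.80, adjusted p = 0.00327), Sln (-5.31 ± 0.999) and Myl7 (-4.70 ± 0.72) fell. In all, 1734 of 18223 genes changed, 1222 upward and 512 downward.

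Of 26 lists, 12 were called. Macrophage genes were higher (median 4.48, adjusted p = 4.2e-28, estimated-correlation p = 0.142, 21 rose, 1 of 22 did not pass, 22 rose adjusted over the list alone). They include the protease Ctss (5.14 ± 0.47) and the receptor Cx3cr1 (4.07 ± 0.43). Neutrophil genes were higher (median 7.12, adjusted p = 1.1e-08, estimated-correlation p = 0.142, 7 rose, 4 of 11 did not pass, 10 rose adjusted over the list alone). So were cytokines (median 4.22, adjusted p = 6.0e-10, estimated-correlation p = 0.476, 11 rose, 7 of 18 did not pass, 14 rose adjusted over the list alone), with Il1b (7.18 ± 1.12). The integrated stress response (median 0.53, adjusted p = 8.6e-04, estimated-correlation p = 0.142, 3 rose, 11 of 14 did not pass, 4 rose adjusted over the list alone) includes Slc7a11 (7.85 ± 0.67). Also higher was hypoxia and glycolysis (median 0.80, adjusted p = 0.00646, estimated-correlation p = 0.860, 5 rose, 23 of 28 did not pass, 9 rose adjusted over the list alone) with Egln3 (1.87 ± 0.32). Epicardium was higher (median 3.97, adjusted p = 0.00120, estimated-correlation p = 0.545, 3 rose, 5 of 8 did not pass, 7 rose adjusted over the list alone) with Krt19 (3.11 ± 0.55). The cell cycle was higher (median 1.12, adjusted p = 8.0e-05, estimated-correlation p = 0.809, 3 rose, 25 of 28 did not pass, 17 rose and 1 fell adjusted over the list alone) with Tyms (1.53 ± 0.23). Mitochondrially encoded genes were higher (median 3.32, adjusted p = 1.8e-07, estimated-correlation p = 0.545, 3 rose, 10 of 13 did not pass, 13 rose adjusted over the list alone) with mt-Nd5 (3.25 ± 0.85). The share of counts from mitochondrial genes was 17.6 and 18.0% in the wild-type libraries of day 3 and 1.87 to 2.40% at homeostasis. Atrial markers were lower (median -4.14, adjusted p = 1.1e-08, estimated-correlation p = 0.142, 5 fell, 3 of 8 did not pass, 6 fell adjusted over the list alone). Endothelial identity was lower (median -0.69, adjusted p = 0.00646, estimated-correlation p = 0.860, 22 of 22 did not pass, 0 adjusted over the list alone), as were pericytes and smooth muscle (median -0.53, adjusted p = 0.0181, estimated-correlation p = 0.809, 14 of 14 did not pass, 0 adjusted over the list alone). The sex-linked list was lower (median -9.77, adjusted p = 8.8e-30, estimated-correlation p = 5.6e-04, 1 rose, 4 fell, 0 of 5 did not pass, 1 rose and 4 fell adjusted over the list alone). The sex-linked list is the one call that held with an estimated correlation, and fry called 7 of the 12. The count was 677, 623 and 711 without homeostasis libraries 1, 2 and 3. It was 645 and 442 without day 3 libraries 1 and 2, a fit in which the lone day 3 sample is assumed to vary like the other groups. It was 6798 without the Q150X library 2, which enters the estimate of the spread. Some calls were lost when 1 library was left out: mt-Nd5 with each of these 5, Sln and Krt19 with homeostasis libraries 2 or 3 or day 3 library 2, Sln also with homeostasis library 1. Egln3 lost it with either day 3 library and Tyms with day 3 library 2 (adjusted p 0.0506 to 0.210). With the replicate block Sln and mt-Nd5 lost theirs (0.0561 and 0.124), and mt-Nd5 without a filter (0.0734). The cell cycle list lost its call without day 3 library 2 (0.46) and epicardium without the Q150X library 2 (3.98).

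In wild-type cardiomyocytes 3 days after MI (n = 3 against 3), lists of stress, division and matrix ranked higher and those of contraction and energy supply lower. Fry called them too, camera with an estimated correlation none of them. The natriuretic peptide Nppa (4.35 ± 0.48, 362 ± 103 against 17.8 ± 3.37 CPM, adjusted p = 5.7e-04), Ankrd1 (1.09 ± 0.17) and Myh7 (1.72 ± 0.33) rose. The 6 largest rises were Spp1 (11.05 ± 0.96), Serpina3n (6.80 ± 0.56), Tnc (6.42 ± 0.41), Timp1 (6.31 ± 0.66), Ctss (5.97 ± 0.60) and Lox (5.92 ± 0.68). Spp1 had 3 counts at homeostasis, so its pooled ratio of 2282-fold has a counting interval of 780.5 to 11065. The largest falls were Plekhh1 (-2.49 ± 0.31, adjusted p = 1.0e-04), Timp4 (-2.26 ± 0.67), Arrdc2 (-2.04 ± 0.43), the endothelial Rgcc (-2.01 ± 0.38) and Car4 (-1.95 ± 0.51), and the clock gene Arntl (-1.99 ± 0.48). In all, 2634 of 15169 genes changed, 1539 upward and 1095 downward.

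The cell cycle list was higher (median 2.44, adjusted p = 4.9e-17, estimated-correlation p = 0.102, 23 rose, 5 of 28 did not pass, 25 rose adjusted over the list alone). It holds the mitotic gene Bub1 (5.44 ± 0.68) and the replication gene Mcm6 (2.26 ± 0.31). Cardiac stress genes were higher (median 0.71, adjusted p = 4.4e-07, estimated-correlation p = 0.102, 7 rose, 7 of 14 did not pass, 9 rose adjusted over the list alone). The mitochondrial creatine kinase Ckmt2 (-0.72 ± 0.11) and the light chain Myl2 (-0.61 ± 0.10) fell within cardiomyocyte structure (median -0.34, adjusted p = 3.4e-05, estimated-correlation p = 0.244, 10 fell, 10 of 20 did not pass, 11 fell adjusted over the list alone). Oxidative phosphorylation was lower (median -0.40, adjusted p = 8.2e-16, estimated-correlation p = 0.240, 29 fell, 17 of 46 did not pass, 35 fell adjusted over the list alone), with Cox7a1 (-1.04 ± 0.15) and Ndufs3 (-0.57 ± 0.10). Fatty acid oxidation was lower (median -0.45, adjusted p = 3.9e-08, estimated-correlation p = 0.240, 1 rose, 15 fell, 8 of 24 did not pass, 1 rose and 18 fell adjusted over the list alone), with the dehydrogenase Hadh (-0.76 ± 0.13). Mitochondrially encoded genes were lower (median -0.60, adjusted p = 1.2e-06, estimated-correlation p = 0.161, 9 fell, 4 of 13 did not pass, 10 fell adjusted over the list alone), with mt-Nd5 (-0.73 ± 0.13).

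Markers of other cells were higher too, so the source of cell cycle RNA is open. Among macrophage genes (median 4.64, adjusted p = 3.4e-34, estimated-correlation p = 0.0530, 21 rose, 1 of 22 did not pass, 21 rose adjusted over the list alone) is C1qa (3.93 ± 0.46). Matrix (median 2.29, adjusted p = 2.7e-30, estimated-correlation p = 0.102, 24 rose, 9 of 33 did not pass, 28 rose adjusted over the list alone) includes Col12a1 (5.02 ± 0.46). Cytokines (median 4.10, adjusted p = 7.0e-21, estimated-correlation p = 0.0545, 16 rose, 1 of 17 did not pass, 16 rose adjusted over the list alone) include Il6 (4.01 ± 0.41). The epicardium list (median 3.56, adjusted p = 3.7e-04, estimated-correlation p = 0.151, 5 rose, 3 of 8 did not pass, 5 rose adjusted over the list alone) includes the keratin Krt18 (3.80 ± 0.62). Genes without a count in a group enter medians at a fitted value, and with them at a floor of 3 counts per library the median is 4.29 for macrophages and 3.37 for cytokines. The interferon response was higher (median 0.43, adjusted p = 0.00273, estimated-correlation p = 0.387, 2 rose, 18 of 20 did not pass, 6 rose adjusted over the list alone). The integrated stress response was higher (median 0.92, adjusted p = 0.00210, estimated-correlation p = 0.200, 8 rose, 6 of 14 did not pass, 9 rose and 1 fell adjusted over the list alone) with Slc7a11 (4.22 ± 0.73). Atrial markers were higher (median 0.36, adjusted p = 0.00586, estimated-correlation p = 0.102, 2 rose, 4 of 6 did not pass, 2 rose and 1 fell adjusted over the list alone) and endothelial identity lower (median -0.50, adjusted p = 0.00579, estimated-correlation p = 0.544, 3 fell, 19 of 22 did not pass, 3 fell adjusted over the list alone). Of the 15 lists called of 22, the remaining one, the immediate early list (-0.66, estimated-correlation p 0.544), lost its call without any of 4 libraries (-0.79 to -0.48), and fry called 13. The count was 1583 without homeostasis library 3 and 1352 without day 3 library 1. With library size as the sole scaling 4340 genes changed, 4109 of them upward, because the median of all genes moved to 0.30. Myl2 and Ndufs3 then lost their calls, and the directions above held. Timp4 lost its call without any of the 3 day 3 libraries or homeostasis library 2 or 3, Arntl without day 3 library 2 or 3, and Car4 without day 3 library 1 or 2 or homeostasis library 2 (adjusted p 0.0510 to 0.128). Timp4 also lost it with voom, without a filter and with the compared groups alone (0.0620 to 0.116). Endothelial identity lost its call without homeostasis library 2 (-0.06).

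**Figure D2:**
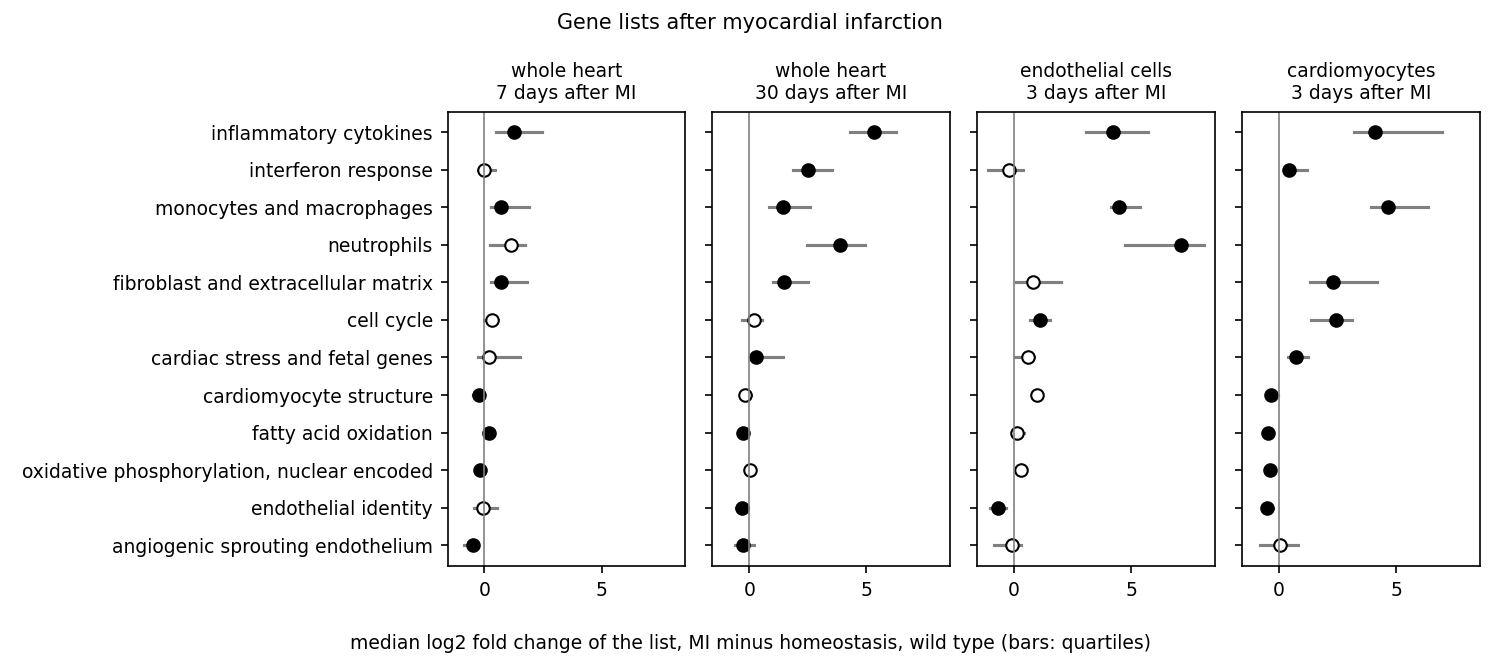
Median log2 fold change (horizontal axis) of the lists in the 4 comparisons of MI with homeostasis in wild type; bars span the quartiles of a list's genes, filled points are lists called by camera and open points are not. Macrophage and cytokine lists lie to the right of 0 in all 4, from 0.72 to 4.64 for macrophages; neutrophils were not measured in cardiomyocytes.

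At homeostasis, whole hearts of Q150X (n = 3 against 3) had endothelial lists ranked lower and cardiomyocyte structure higher, with no single gene called. Of 22 genes of endothelial identity 21 were lower (median -0.31, adjusted p = 1.2e-08, estimated-correlation p = 0.467), among them Tek (-0.49 ± 0.16). Angiogenic sprouting was lower (median -0.22, adjusted p = 0.00801, estimated-correlation p = 0.773) with Apold1 (-1.01 ± 0.49). All 20 cardiomyocyte structure genes had positive values (median 0.18, adjusted p = 0.00236, estimated-correlation p = 0.744), for example Mybpc3 (0.37 ± 0.25). Oxidative phosphorylation (median 0.12, adjusted p = 0.00434, estimated-correlation p = 0.884) with Ndufa9 (0.34 ± 0.16) ranked higher. The immediate early list (median -0.51, adjusted p = 4.6e-04, estimated-correlation p = 0.607) with Nr4a1 (-1.41 ± 0.50) ranked lower. The other 3 of the 8 called lists (estimated-correlation p 0.607 to 0.884) were lost without at least 1 library. Fry called none. The smallest p of genes so picked belonged to Slc41a3 (1.14 ± 0.29), Hist1h1e (1.25 ± 0.34) and Sox4 (0.72 ± 0.20) upward and Ramp3 (-0.91 ± 0.24), Cry1 (-0.72 ± 0.20) and Irf2bp2 (-0.66 ± 0.18) downward, each with adjusted p = 1 (smallest of all genes 0.469). In all 8 lists 0 genes passed, also adjusted over the list alone. edgeR called 0 of 17845 genes (504 at unadjusted p under 0.05), DESeq2 3 and voom 0. These list differences rest on the number 1 libraries, which hold atrial, fat and red cell transcripts (Hba-a1 759 and 327 CPM against at most 64.3). Without Q150X library 1 all 8 calls were lost (endothelial identity -0.13), without wild-type library 1 all but that of endothelial identity. With both left out, angiogenic sprouting was 0.08, cardiomyocyte structure -0.04, endothelial identity 0.01, the immediate early list 0.15, and oxidative phosphorylation -0.11, called lower. With library size alone the last lost its call (0.015).

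In endothelial cells at homeostasis (n = 3 against 3), the cell cycle list ranked lower in Q150X by camera at the preset correlation alone. Of the 28 genes 26 were lower (median -0.58, adjusted p = 7.4e-19, estimated-correlation p = 0.963), with the mitotic genes Cenpf (-1.05 ± 0.34) and Ccnb1 (-1.12 ± 0.42). Clock genes ranked higher (median 0.35, adjusted p = 0.00172, estimated-correlation p = 0.963) with Per1 (0.74 ± 0.29). Epicardial genes, near the detection limit in most libraries, ranked lower (median -2.50, adjusted p = 2.5e-05, estimated-correlation p = 0.963). Of genes picked by p, upward were Ss18l1 (0.63 ± 0.21), Epop (0.72 ± 0.24) and AC141429.2 (0.72 ± 0.22). Downward they were the insulin-degrading enzyme Ide (-0.82 ± 0.18, 52.1 ± 3.75 against 92.3 ± 9.71 CPM, adjusted p = 1), Cenpf and Sema5b (-5.59 ± 1.86). In these 3 lists 0 genes passed, also adjusted over the list alone. edgeR called 0 of 18223 genes (168 at unadjusted p under 0.05), DESeq2 1 and voom 0. Simulated 2-fold changes were recovered for 1% of genes and 4-fold for 39%, so this fit, day 3 included, hardly detects smaller ones. The cell cycle call held without each library in turn. The clock list lost its call without wild-type library 3 (0.34) or Q150X library 3 (-0.01), and the epicardial list without wild-type library 1 (-0.08).

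Cardiomyocytes at homeostasis (n = 3 against 3) had lists of endothelial, mural and other non-cardiomyocyte cells ranked lower in Q150X by camera at the preset correlation alone. Endothelial identity was lower (median -0.83, adjusted p = 1.8e-11, estimated-correlation p = 0.361) with Ecscr (-1.73 ± 0.41). Angiogenic sprouting was lower (median -0.69, adjusted p = 1.5e-07, estimated-correlation p = 0.361) with the laminin Lamb1 (-0.56 ± 0.11). Pericytes and smooth muscle were lower (median -0.48, adjusted p = 7.0e-04, estimated-correlation p = 0.361) with Kcnj8 (-1.37 ± 0.36). VEGF ligands and receptors were lower (median -0.69, adjusted p = 0.0112, estimated-correlation p = 0.361) with Vegfc (-1.56 ± 0.47). So was the interferon response (median -0.71, adjusted p = 5.8e-05, estimated-correlation p = 0.361) with Ifit1 (-1.77 ± 0.40). So were mitochondrially encoded genes (median -0.39, adjusted p = 1.5e-05, estimated-correlation p = 0.361) with mt-Nd5 (-0.41 ± 0.13), and the mitochondrial share of counts was 36.9 to 39.0% against 39.6 to 49.96%. All 46 measured genes of oxidative phosphorylation were positive (median 0.17, adjusted p = 6.9e-08, estimated-correlation p = 0.493), with Ndufa2 (0.44 ± 0.13). Hypoxia and glycolysis (median 0.11, adjusted p = 0.00851, estimated-correlation p = 0.361) with P4ha1 (0.53 ± 0.12) and Egln3 (0.74 ± 0.19) was higher. The other 5 of the 13 called lists lost their calls with an estimated correlation (adjusted p 0.493 to 0.495) and without at least 1 library (median then after the semicolon): matrix (-0.58; -0.33), cytokines (-1.14; -0.23) and macrophages (-0.71; -0.86), lower, and cardiac stress (0.27; 0.11 to 0.24) and cardiomyocyte structure (0.15; 0.061), higher. With genes without a count at a floor of 3 counts, cytokines are at -1.08 and macrophages at -0.63.

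The genes picked by p in these cells were Tubb4b (0.59 ± 0.10, adjusted p = 0.109) and Tuba8 (0.94 ± 0.16) and Manf (0.67 ± 0.13) upward. Downward they were Mdm4 (-0.63 ± 0.11), Abca8b (-1.55 ± 0.28) and Adamts6 (-0.96 ± 0.18). edgeR called 0 of 15169 genes (2009 at unadjusted p under 0.05), DESeq2 258 and voom 8. None of the genes in the 13 called lists passed over all genes. Adjusted over the list alone, 10 fell in endothelial identity, 7 in angiogenic sprouting, 7 in interferon response, 4 in pericytes, 4 in mitochondrially encoded genes and 1 in VEGF ligands and receptors, and 4 rose in hypoxia and glycolysis. edgeR called 543 genes without a filter, 12 with the block, 3 with library size alone, 38 without wild-type library 1 and 49 without Q150X library 2. Called with each library left out were endothelial identity, angiogenic sprouting, pericytes, interferon response, mitochondrially encoded genes and oxidative phosphorylation. VEGF ligands and receptors lost their call without wild-type library 2 (-0.24) or Q150X library 1 (-0.39), and hypoxia and glycolysis without Q150X library 3 (0.09).

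At 7 days after MI, the macrophage list ranked higher in Q150X hearts (n = 4 against 4) by camera at the preset correlation alone. All 22 genes had positive values (median 0.64, adjusted p = 1.2e-13, estimated-correlation p = 0.534), with Ly6c2 (3.00 ± 0.84) and Fcgr1 (1.48 ± 0.51). Mitochondrially encoded genes were lower in 13 of 13 (median -0.23, adjusted p = 1.3e-05, estimated-correlation p = 0.591), with mt-Co2 (-0.54 ± 0.21). Pericytes and smooth muscle were lower (median -0.17, adjusted p = 0.00119, estimated-correlation p = 0.534) with Notch3 (-0.43 ± 0.17). Cytokines ranked higher (median 1.01, adjusted p = 4.2e-04, estimated-correlation p = 0.591) with Ccl5 (2.71 ± 0.94). The interferon response did too (median 0.53, adjusted p = 6.9e-08, estimated-correlation p = 0.591) with Gbp2 (2.28 ± 0.73, 109.6 ± 169.5 against 22.6 ± 3.15 CPM, adjusted p = 1). Matrix ranked higher (0.28) and cardiomyocyte structure (-0.07) and fatty acid oxidation (-0.15) lower, and these 3 of the 8 calls were lost with an estimated correlation (adjusted p 0.591 to 0.744) and without at least 1 library (0.062 to 0.25, -0.089 to -0.019 and -0.11) or, for cardiomyocyte structure, with library size alone (-0.014). The Q150X library 2 of this day held 364 CPM of Gbp2 against 18.0 to 33.9 in the other 7. Picked by p were BC023105 (5.16 ± 1.25), H2-K1 (1.15 ± 0.30) and Adam8 (1.06 ± 0.28) upward and Slc22a3 (-0.74 ± 0.19), Peg10 (-4.18 ± 1.12) and Adi1 (-0.40 ± 0.12) downward, all with adjusted p = 1. Wild-type library 4 holds 114 CPM of Peg10, which is also a placental gene. In the 8 called lists 0 genes passed, also adjusted over the list alone. edgeR called 0 of 17845 genes (561 at unadjusted p under 0.05), DESeq2 4 and voom 0. The calls of macrophages, mitochondrially encoded genes and pericytes held with each library left out. Without Q150X library 2 the macrophage median was 0.52, Ly6c2 0.66 and Fcgr1 0.66. Then interferon response (0.15) and cytokines (0.14, ranked lower) lost theirs, and without wild-type library 3 cytokines (0.65) did.

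At 30 days after MI, inflammatory genes such as Ptx3 and Il6, high in the wild-type hearts of that day, were lower in Q150X hearts (n = 4 against 3). Lists of macrophages, lymphocytes, matrix and the cell cycle ranked higher without a single gene past the test over all genes, and lost their calls with an estimated correlation (adjusted p 0.134 to 0.506). The 10 largest falls begin with Ptx3 (-5.06 ± 0.72, 2.68 ± 0.832 against 90.0 ± 98.4 CPM, adjusted p = 0.00758), Has1 (-3.40 ± 0.66), the cytokine Il6 (-3.17 ± 0.67), Pfkfb3 (-3.16 ± 0.54) and Ccl2 (-3.13 ± 0.65). Next come Ch25h (-2.86 ± 0.55), Rgs16 (-2.68 ± 0.44), Bcl3 (-2.56 ± 0.49), Myc (-2.26 ± 0.37) and Tnfaip2 (-2.20 ± 0.42). Large rises begin with Cd5l (4.03 ± 0.76, 27.6 ± 19.8 against 1.68 ± 0.958 CPM, adjusted p = 0.0344), Trim46 (1.52 ± 0.33), Otulinl (1.45 ± 0.31), Kif26b (1.39 ± 0.27) and Btbd19 (1.26 ± 0.28). They go on with Apobec1 (1.21 ± 0.24), Arhgap45 (1.20 ± 0.24), BC037034 (1.19 ± 0.19) and Myo7a (1.13 ± 0.20). In all, 79 of 17845 genes changed, 27 upward and 52 downward.

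Inflammatory cytokines were lower as a list (median -1.49, adjusted p = 1.4e-07, estimated-correlation p = 0.284), also with Ptgs2 (-2.27 ± 0.54): 2 fell and 16 of 18 did not pass (5 fell adjusted over the list alone). Macrophage genes were higher (median 0.83, adjusted p = 2.3e-05, estimated-correlation p = 0.490) with Ccr2 (2.12 ± 0.58). Lymphocytes were higher (median 1.49, adjusted p = 3.2e-07, estimated-correlation p = 0.134) with the B-cell gene Cd79b (1.63 ± 0.48). The cell cycle was higher (median 0.69, adjusted p = 1.4e-08, estimated-correlation p = 0.284) with Birc5 (1.80 ± 0.44). Matrix was higher (median 0.64, adjusted p = 6.7e-06, estimated-correlation p = 0.506) with Col5a2 (1.17 ± 0.33). Lymphatic endothelium was too (median 0.44, adjusted p = 0.00756, estimated-correlation p = 0.433) with Lyve1 (0.65 ± 0.19). Lower were fatty acid oxidation (median -0.39, adjusted p = 6.4e-10, estimated-correlation p = 0.284) with Hadh (-0.50 ± 0.14) and oxidative phosphorylation (median -0.26, adjusted p = 7.1e-11, estimated-correlation p = 0.433) with Uqcrc1 (-0.54 ± 0.16). Cardiomyocyte structure was lower (median -0.25, adjusted p = 2.7e-05, estimated-correlation p = 0.425) with Atp2a2 (-0.67 ± 0.20). So was the immediate early list (median -0.46, adjusted p = 0.00733, estimated-correlation p = 0.506) with Socs3 (-2.20 ± 0.50). So were mitochondrially encoded genes (median -0.19, adjusted p = 0.0166, estimated-correlation p = 0.552) with mt-Cytb (-0.26 ± 0.17) and pericytes (median -0.23, adjusted p = 0.00756, estimated-correlation p = 0.425) with Vtn (-0.59 ± 0.16). Besides Il6 and Ccl2, 0 genes of the 12 lists passed over all genes. Adjusted over the list alone, 14 of 24 fell in fatty acid oxidation, 4 of 14 in pericytes (1 rose) and 1 in the immediate early list. By that measure 5 of 28 rose in the cell cycle, 2 in macrophages, 2 in lymphatic endothelium and 1 in lymphocytes. Of the 12 lists, fry called lymphocytes.

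The set of called genes changes with single libraries. The count was 7 without wild-type library 1, 154 without 2 and 0 without 3, and 9, 8 and 223 without Q150X libraries 1, 3 and 4. It was 476 with replicate number as a block, 454 with DESeq2 (75 shared), and 1751 with voom (78 shared). It was 714 without the libraries of other groups that stand apart (79 shared), 46 with library size as the sole scaling and 0 in a fit of these 7 libraries alone. Of the 19 genes named first, all lost their calls without wild-type library 3, 18 without wild-type library 1 (Ptx3 kept it) and 17 without Q150X library 1 or 3 (all but Ptx3 and BC037034). Calls were lost by 6 without wild-type library 2 or Q150X library 2 and Ccl2 without Q150X library 4 (adjusted p 0.0510 to 0.274). Without wild-type library 3 Ptx3 was at -3.70 and Il6 at -2.59. With library size alone Trim46, Il6 and Ccl2 lost theirs, with the block 7 of the 19 and without a filter 9 (0.0521 to 0.125), Il6 and Ccl2 among them each time. Calls of the lists held with each library left out except the immediate early list (-0.45 without wild-type library 2, -0.27 without Q150X library 1), mitochondrially encoded genes (-0.09 without wild-type library 1, -0.13 and -0.17 without Q150X libraries 3 and 4, -0.18 with the block) and pericytes (-0.18 without Q150X library 1).

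**Figure D3:**
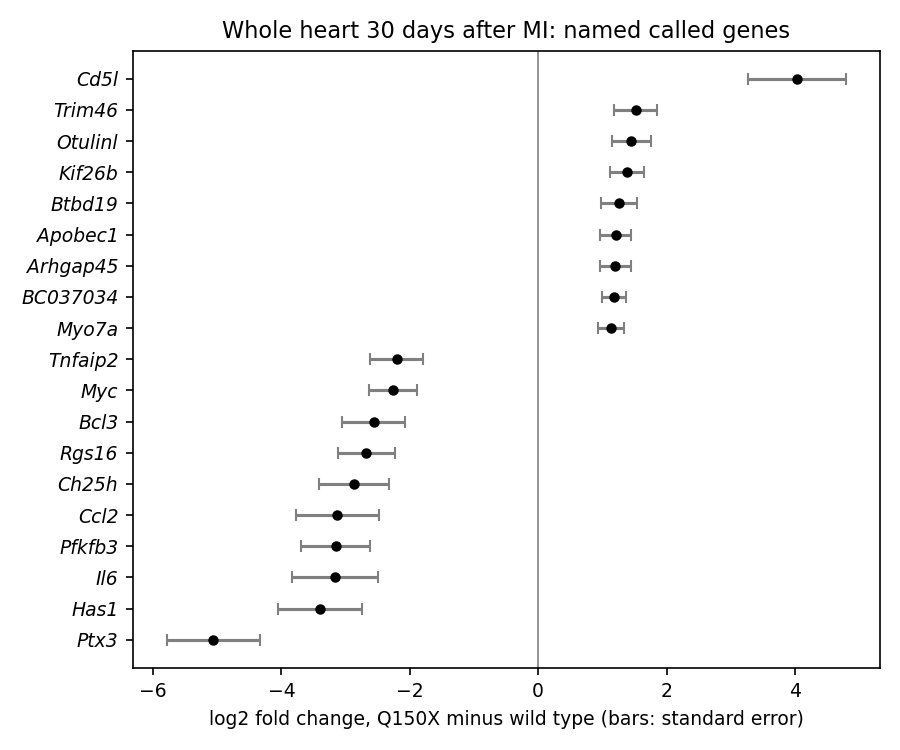
Log2 fold changes (horizontal axis, Q150X minus wild type) of 19 genes with large called changes between genotypes in whole heart 30 days after MI; bars are the SE. Ptx3, with the largest fall, stands at -5.06 ± 0.72 and Cd5l, with the largest rise, at 4.03 ± 0.76.

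In endothelial cells 3 days after MI (n = 2 against 2), vascular and stromal lists ranked lower in Q150X, most so in library 2, and that library alone held many lymphocyte transcripts. Endothelial identity was lower (median -1.23, adjusted p = 2.3e-07, estimated-correlation p = 0.616) with Vwf (-1.86 ± 0.48). Angiogenic sprouting was lower (median -1.67, adjusted p = 1.6e-09, estimated-correlation p = 0.616) with Esm1 (-1.82 ± 0.38). VEGF ligands and receptors were lower (median -1.23, adjusted p = 2.7e-04, estimated-correlation p = 0.616) with the lymphatic receptor Flt4 (-1.81 ± 0.53). Lymphatic endothelium was lower (median -1.82, adjusted p = 2.2e-05, estimated-correlation p = 0.616) with Ccl21a (-2.03 ± 0.43). So were pericytes (median -1.96, adjusted p = 2.3e-09, estimated-correlation p = 0.616) with Notch3 (-1.74 ± 0.33). So was matrix (median -1.68, adjusted p = 9.3e-13, estimated-correlation p = 0.616) with Comp (-2.12 ± 0.28). Lymphocyte genes were higher (median 4.66, adjusted p = 1.4e-07, estimated-correlation p = 0.616) with Cd3e (5.29 ± 1.31). Cardiomyocyte structure (median -0.36, adjusted p = 0.0182, estimated-correlation p = 0.923) ranked lower, as did 4 more lists (estimated-correlation p 0.616 to 0.841) whose calls were lost without at least 1 library. Fry called none. Picked by p were Lcp2 (1.68 ± 0.22, adjusted p = 0.124), Arl5c (2.72 ± 0.37) and Slc16a6 (1.57 ± 0.22) upward and Pthlh (-2.50 ± 0.33), Comp and Megf6 (-2.57 ± 0.37) downward. edgeR called 0 of 18223 genes (4223 at unadjusted p under 0.05), DESeq2 2335 and voom 0. None of the genes in the 12 called lists passed over all genes. Adjusted over the list alone, 14 of 16 rose in lymphocytes, and 12 of 14 fell in pericytes, 5 in lymphatic endothelium, 3 in angiogenic sprouting (1 rose) and 2 in matrix. The count was 162 with library size alone, 4 without a filter, 10498 without Q150X library 1, 1151 without Q150X library 2 (553 upward) and 1 without wild-type library 2. A lone sample is then assumed to vary like the other groups. Calls that held with each library left out were endothelial identity, angiogenic sprouting, VEGF ligands and receptors, lymphatic endothelium, pericytes and matrix. Without Q150X library 2 their medians were -0.52, -0.89, -0.44, -1.25, -1.37 and -0.85 in this order, and Vwf was -1.34. The remaining library 1 has the highest median levels of macrophage (8.07 log2 CPM) and cardiomyocyte genes (6.70) of the 10 endothelial libraries. Without library 2, lymphocytes were at 0.42 without a call, and cardiomyocyte structure was called higher at 0.57. The mitochondrial share of counts was 35.5% in Q150X library 1 and 3.65% in library 2.

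In cardiomyocytes 3 days after MI (n = 3 against 3) no gene was called between the genotypes. The integrated stress response (median -0.28, adjusted p = 7.0e-05, estimated-correlation p = 0.398) with Mthfd2 (-1.38 ± 0.53) and Asns (-1.83 ± 0.77) ranked lower in Q150X. Angiogenic sprouting (median 0.25, adjusted p = 9.2e-05, estimated-correlation p = 0.838) with Plvap (0.81 ± 0.37) and Sox18 (0.69 ± 0.35) ranked higher. Hypoxia and glycolysis ranked higher by little (median 0.03, adjusted p = 0.0463, estimated-correlation p = 0.838), with Slc16a3 (0.91 ± 0.25). So did the cell cycle (0.25; -0.032 to 0.31 where its call was lost), endothelial identity (0.24; 0.14 to 0.27), matrix (0.18; -0.037 to 0.24) and the immediate early list (0.20; -0.12 to 0.24), and mitochondrially encoded genes ranked lower (-0.13; -0.12 to -0.084). Each of these 5 had an estimated-correlation p of 0.838. Genes picked by p were Slc16a3, Slc52a2 (0.75 ± 0.23) and Ccrl2 (0.66 ± 0.20) upward and Abat (-0.64 ± 0.16), Zkscan3 (-0.56 ± 0.14) and Smim13 (-0.37 ± 0.10) downward, all with adjusted p = 1 (smallest of all genes 0.317). In the 8 called lists 0 genes passed, also adjusted over the list alone. edgeR called 0 of 15169 genes (254 at unadjusted p under 0.05), DESeq2 2, voom 1, and edgeR 8 without a filter and 1 without wild-type library 1. Each of the 8 calls was lost without at least 1 library, and those of the cell cycle, matrix and the immediate early list also with library size alone. Lost were the integrated stress response without wild-type library 1 (-0.19), angiogenic sprouting without library 3 of wild type (0.08) or Q150X (0.14), and hypoxia and glycolysis without wild-type library 1 (0.04) or Q150X library 1 (0.08) or 3 (0.04) or with the block (0.025).

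Whether MI acted differently in the genotypes was tested as an interaction, the genotype effect after MI minus that at homeostasis. No gene was called by edgeR in any of the 4 with the filter on low counts, and 219 in cardiomyocytes without it. In hearts at day 7 (588 genes at unadjusted p under 0.05, DESeq2 1, voom 0, smallest adjusted p of all genes 0.532) those picked by p were Tlr13 (2.22 ± 0.53) and Tlr7 (1.57 ± 0.45) and Tmem254a (1.90 ± 0.52) upward. Downward they were Slc22a3 (-1.08 ± 0.29), Lsmem1 (-0.88 ± 0.24) and Epha4 (-0.82 ± 0.24). At day 30 (1724 genes at unadjusted p under 0.05, DESeq2 54, voom 1) they were BC037034 (1.40 ± 0.27, adjusted p = 0.253), Fgd3 (2.13 ± 0.46) and Skap2 (1.10 ± 0.24) upward. Downward they were Sbno2 (-1.55 ± 0.32), Lrrc8b (-1.21 ± 0.25) and Bhlhe40 (-1.23 ± 0.26). So the day 30 differences above are not shown to differ from those at homeostasis gene by gene.

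In endothelial cells, where sex changes with time, the interaction is equally one of genotype with sex. It (2291 genes at unadjusted p under 0.05, DESeq2 478, voom 0) had as genes picked by p Dapp1 (1.54 ± 0.23, adjusted p = 0.373), Sema4d (2.01 ± 0.33) and Slc16a6 (1.69 ± 0.29) upward. Downward they were Pthlh (-2.50 ± 0.40), Cytl1 (-2.28 ± 0.38) and Cacnb4 (-2.29 ± 0.40). In cardiomyocytes (1186 genes, DESeq2 20, voom 0) they were Mtss1 (1.24 ± 0.26, adjusted p = 0.495), Ldb2 (1.84 ± 0.39) and Map6 (1.58 ± 0.36) upward. Downward they were Tubb4b (-0.69 ± 0.14), Tuba8 (-1.02 ± 0.22) and Agpat5 (-0.69 ± 0.17). Camera called 11, 11, 14 and 12 lists for the interactions of hearts at day 7, hearts at day 30, endothelial cells and cardiomyocytes, and neither camera with an estimated correlation (adjusted p at least 0.634, 0.454, 0.629 and 0.400) nor fry called any. Simulated interactions of 4-fold were recovered for 57% of genes in hearts at day 7, 58% at day 30, 0% in endothelial cells and 67% in cardiomyocytes. Without day 30 wild-type library 2, edgeR called 30 genes in the day 30 interaction, and 1 with the block. In endothelial cells it called 8765 without Q150X library 1 and 347 without Q150X library 2, and in cardiomyocytes 1 without the homeostasis Q150X library 2.

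Around Vegfa on chromosome 17, 57 genes within 2 Mb were tested over the 7 genotype comparisons with a stratified permutation test. None passed (smallest adjusted p = 0.320, Enpp4). None of the 79 genes called in hearts at day 30 lies there.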

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

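Tests chosen after the result was seen are the 3 explanations for hearts at day 30, the effect of the genotype in the endothelial library, and the female heart. Lists whose genotype effect differs between MI and homeostasis are given by their median interaction (log2), each called by camera and by neither fry nor camera with an estimated correlation.

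In hearts at day 7 these are the interferon response (0.78), cytokines (0.76), macrophages (0.73), the immediate early list (0.55), lymphatic endothelium (0.51), endothelial identity (0.38), matrix (0.32), mitochondrially encoded genes (-0.39), cardiomyocyte structure (-0.27), fatty acid oxidation (-0.22) and oxidative phosphorylation (-0.15). At day 30 they are lymphocytes (1.65), macrophages (0.80), the cell cycle (0.66), matrix (0.66), lymphatic endothelium (0.61), cytokines (-1.35), fatty acid oxidation (-0.46), cardiomyocyte structure (-0.43), mitochondrially encoded genes (-0.42), oxidative phosphorylation (-0.37) and hypoxia and glycolysis (-0.22). Part of this comes from homeostasis, where the number 1 hearts carry atrial and fat markers.

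In endothelial cells, where Q150X library 2 of day 3 carries lymphocyte RNA and sex changes with time, they are lymphocytes (4.57), the cell cycle (0.56), erythroid genes (-2.63), pericytes (-2.08), atrial markers (-1.89), matrix (-1.57), angiogenic sprouting (-1.56), lymphatic endothelium (-1.47), endothelial identity (-1.44), clock genes (-1.20), VEGF ligands and receptors (-1.12), cardiac stress (-0.55), the immediate early list (-0.38) and cardiomyocyte structure (-0.31). In cardiomyocytes they are cytokines (1.38), macrophages (1.29), endothelial identity (1.04), angiogenic sprouting (0.99), pericytes (0.84), the interferon response (0.82), the cell cycle (0.81), matrix (0.77), VEGF ligands and receptors (0.75), mitochondrially encoded genes (0.26), oxidative phosphorylation (-0.14) and cardiomyocyte structure (-0.13). Part of this too comes from homeostasis, where endothelial identity (-0.83), cytokines (-1.14) and macrophages (-0.71) were lower in Q150X. In 5 of these 48 lists a gene has 0 counts in a group.

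Of 96 series of 4 libraries (genes and list medians within a group), 6 hold a library far from the others, and chance does so in about 1 in 20. The gap to the nearest library as a share of the range was 0.830 for VEGF ligands and receptors in Q150X heart 1 of day 30 (5.36 against 5.89 to 5.99 log2 CPM), 0.916 for Kdr (6.93 against 7.28 to 7.31) and 0.886 for the immediate early list (4.52 against 4.83 to 4.87) in Q150X heart 3 of day 7, and 1 for adipocytes in Q150X heart 4 of day 7 (-3.44 against -3.94, the floor). In wild-type heart 4 of day 7 it was 1 for adipocytes (-3.67 against -3.94) and 0.890 for lymphocytes (-1.60 against -2.03 to -1.98).

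The 79 genes called between genotypes in hearts at day 30 include cytokines and early response genes that fell. A smaller share of macrophages is not seen (list median 0.83, quartiles 0.52 to 1.35), and neutrophils were not tested for this. A difference in depth is excluded (ratio of the mean total counts 1.0005). Tissue handling stays open, since the immediate early list has a median of -0.46 (quartiles -0.94 to 0.22) and the genes called lower one of -1.58. The genotype as the cause was not separated from handling, and 2 of 35 splits of the libraries called as many genes (highest other 117), so chance is not excluded.

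The lymphocyte genes of Q150X endothelial library 2 of day 3 may come from thymus RNA: all 8 genes of double-positive thymocytes, written down before they were looked up, lie over 2-fold above every other endothelial library, with Cd24a highest at 352 CPM. Of 6 genes of thymic epithelium 1 does, with Ccl25 highest at 2.15 CPM, so whole thymus and thymocytes alone are not told apart. Mature T cells of the infarct are excluded as the whole source by Rag2, 416-fold above the highest other library or the floor. An effect of the genotype is excluded by Q150X library 1, where the median difference of these genes from wild type is 0.050, against 4.07 in library 2. When tissue or RNA was mixed in stays open.

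The placental genes of wild-type heart 4 of day 7 may come from placenta RNA, since 12 of 13 trophoblast genes written down beforehand lie above every other heart library, with Tpbpa highest at 467 CPM. A female heart is excluded by 78.8 CPM of the Y-linked Ddx3y. No biological explanation was tested here.

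Other splits of the libraries were run for each comparison with 3 or more libraries per group. For 3 against 3 the 10 splits are too few for a share under 0.05, and the real split called 1594 genes (1 at most in others) for MI in hearts at day 30 and 2634 (0) for MI in cardiomyocytes. Where the real split calls 0 genes, all splits (10, 35 or 50) call as many, so no verdict follows. The highest others were 2381 in hearts, 0 in endothelial cells and 1 in cardiomyocytes at homeostasis, 29 in cardiomyocytes at day 3, 1 for the genotype in hearts at day 7, and 164, 692 and 1 for the interactions of hearts at days 7 and 30 and of cardiomyocytes. The 2381 genes point to a structure of the samples: the 4 splits that keep the number 1 hearts together call 968 to 2381, the other 2 that part 1 pair call 0, and the 4 that part all 3 pairs, the real one included, call 0. For MI in hearts at day 7 chance is excluded (1 of 35 splits, 2448 genes against at most 537). Chance is not excluded for the genotype at day 30 without the libraries that stand apart (2 of 35, 714 against 1665). The 164 and 692 genes again point to a structure of the samples.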

How the results depend on the processing

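Voom, leaving out the libraries that stand apart, and a block at homeostasis only were added after the data were examined. The cause of the changes below was not tested, except where a value is given. Counts are of called genes, with those in the report in parentheses. With library size alone there were 46 (79) for the genotype in hearts at day 30, 162 (0) in endothelial cells at day 3 and 3 (0) in cardiomyocytes at homeostasis, and 4340 (2634) for MI in cardiomyocytes, where the median of all genes moved to 0.30. This scaling also moved that median to 0.20 for the genotype in hearts at day 30, 0.14 and 0.27 for the interactions at days 7 and 30 and -0.14 for MI in endothelial cells. Without a filter there were 49 (79) and 1001 (1594) for genotype and MI in hearts at day 30, 4 (0) in endothelial cells at day 3, and 543, 8 and 219 (each 0) for the genotype in cardiomyocytes at homeostasis and day 3 and their interaction. In a fit of the compared groups alone they were 0 (79) and 715 (1594) for genotype and MI in hearts at day 30 and 7182 (1734) for MI in endothelial cells.

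With replicate number as a block they were 476 (79) for the genotype and 1 (0) for the interaction in hearts at day 30, 686 (1734) for MI in endothelial cells and 12 (0) for the genotype in cardiomyocytes at homeostasis. In hearts at homeostasis only the number 1 pair is told apart. There a block at homeostasis only left the genotype and both interactions at 0 called genes. Matrix (0.35), the immediate early list (0.37) and cytokines (0.89) then lost their calls in the interaction of day 7.

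DESeq2 called 3, 4 and 454 (0, 0, 79) for the genotype in hearts at homeostasis, day 7 and day 30, 1 and 54 (0) for their interactions, 2769 (1594) for MI at day 30, 1 and 2335 (0) for the genotype in endothelial cells at homeostasis and day 3, 3464 (1734) for MI and 478 (0) for the interaction there, and 258, 2 and 20 (0) in cardiomyocytes for the genotype at homeostasis and day 3 and the interaction. Voom called 1751 (79), 5896 (2448), 7185 (1594) and 1 (0) for the genotype at day 30, MI at days 7 and 30 and the interaction at day 30 in hearts, 7652 (1734) for MI in endothelial cells, and 8 and 1 (0) for the genotype in cardiomyocytes at homeostasis and day 3. Without the libraries that stand apart there were 714 (79) and 6221 (1594) for genotype and MI in hearts at day 30, and 1151 (0), 6798 (1734) and 347 (0) for genotype, MI and interaction in endothelial cells.

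With each library left out in turn, the genotype called 0 to 223 (79) in hearts at day 30, 0 to 10498 (0) in endothelial cells at day 3, and 0 to 49 and 0 to 1 (0) in cardiomyocytes at homeostasis and day 3. MI called 1430 to 2322 (2448) and 437 to 4045 (1594) in hearts at days 7 and 30, 442 to 711 (1734) in endothelial cells and 1352 to 2339 (2634) in cardiomyocytes. Interactions called 0 to 30 in hearts at day 30, 0 to 8765 in endothelial cells and 0 to 1 in cardiomyocytes. Of genes near Vegfa, hearts at day 30 had 0 to 1 called (0) with each library left out (Nfkbie without wild-type library 2), 4 with voom (Enpp4, Ubr2, Bysl, Tmem63b) and 1 without the libraries that stand apart (Tmem63b), named after their values were seen.

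Counts of up to 5 comprise these genes, chosen after their values were seen: Ccl6 (block, interaction day 30), Lrrc8b (voom, the same), Liph, Mrpl23-ps1 and Gm3272 (DESeq2, hearts at homeostasis; Liph also in the interaction of day 7), S100g, BC023105, Gm12250 and F830016B08Rik (DESeq2, hearts at day 7), 8030474K03Rik (DESeq2, endothelial cells at homeostasis), Comp, Arl5c, Pthlh and Megf6 (no filter) and Cnn1 (without wild-type library 2) in endothelial cells at day 3, Tuba8, 2210407C18Rik and C130074G19Rik (library size, cardiomyocytes at homeostasis), Capn11, which lies near Vegfa (DESeq2) and an identifier without a symbol (DESeq2, voom, and without wild-type library 1) in cardiomyocytes at day 3, and Wsb1 (without Q150X library 2 of homeostasis) in their interaction.

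The Vegfa difference ranged from -0.55 to 0.25 in hearts at homeostasis with each library left out, -0.020 to 0.16 and -2.30 to 0.21 in endothelial cells at homeostasis and day 3, and -0.073 to 0.16 and -0.23 to 0.081 in cardiomyocytes. Without the libraries that stand apart it was 0.21 in endothelial cells at day 3, and 0.013 with library size alone in cardiomyocytes at day 3. Kdr ranged from -0.54 to 0.10 and -0.19 to 0.022 in hearts at homeostasis and day 7 and -0.15 to 0.0072 in cardiomyocytes at day 3, and Flt1 from -0.48 to 0.020 in hearts at homeostasis, -0.15 to 0.10 in endothelial cells at homeostasis and -0.16 to 0.13 in cardiomyocytes at day 3. Kdr was 0.051 in hearts at day 30 with library size alone. Flt1 was 0.037 with voom and 0.059 without the libraries that stand apart in hearts at homeostasis, and 0.047 with library size alone and 0.077 with voom in cardiomyocytes at day 3. Sema5b ranged from -6.17 to 0.18 in endothelial cells at homeostasis.

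Lists whose camera rank turned had these medians with each library left out. In hearts these were the immediate early list (-0.79 to 0.15) and oxidative phosphorylation (-0.0038 to 0.20) at homeostasis, cytokines at day 7 (0.14 to 1.46), and for the interaction of day 7 matrix (-0.21 to 0.57), the immediate early list (-0.19 to 0.87) and cytokines (-0.38 to 1.12). In cardiomyocytes at day 3 they were the cell cycle (-0.032 to 0.46), matrix (-0.037 to 0.36) and the immediate early list (-0.12 to 0.62). In endothelial cells they were cardiomyocyte structure at day 3 (-4.65 to 0.57) and, for the interaction, cardiac stress (-4.34 to 0.36), cardiomyocyte structure (-4.62 to 0.63) and the immediate early list (-1.70 to 0.22). Without the libraries that stand apart, medians in hearts at homeostasis were 0.083 for angiogenic sprouting, -0.040 for cardiomyocyte structure, 0.15 for the immediate early list and -0.11 for oxidative phosphorylation. For the interaction of day 7 they were -0.013 for fatty acid oxidation, -0.19 for the immediate early list and 0.066 for oxidative phosphorylation. In endothelial cells they were 0.57 for cardiomyocyte structure at day 3, and 0.36, 0.63 and 0.22 for the interactions of cardiac stress, cardiomyocyte structure and the immediate early list. With library size alone the interaction medians of oxidative phosphorylation at day 7 (0.01) and hypoxia and glycolysis at day 30 (0.03) changed sign.

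Of 108 called genes named in the text, 71 kept their call in each alternative and 37 lost it at least once. Of the 118 genes without a call, 63 gained one at least once and 8 turned. Of 154 called lists given with a value 153 lost their call at least once, counting camera with an estimated correlation and fry, and 17 turned at least once.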

Other observations

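The passenger segment around Vegfa was tested after results were seen, and Ide was chosen after a scan of all genes. Ide was lower in Q150X in 7 of 7 genotype comparisons (mean log2 difference -0.43, stratified permutation p = 3e-05). Pooled over the 43 libraries, edgeR called 0 of 20251 genes (1612 at unadjusted p under 0.05, Ide -0.47 ± 0.09 with the smallest adjusted p of 0.158) and voom 8, with Ide (0.0121), Parvg, Pstpip1, Cd300lf and Il18rap, Pde11a, Igha and 1 without a symbol, chosen after their values were seen. The VEGF receptors were at -0.37 ± 0.15 (Kdr) and -0.39 ± 0.14 (Flt1) in the pooled edgeR fit, with unadjusted p of 0.0159 and 0.00876 and adjusted p of 0.558. In endothelial cells at homeostasis Ide stood at 49.1 to 56.3 CPM in Q150X and 85.4 to 103 in wild type. The neighbouring growth factor-binding gene Fgfbp3 had a mean difference of -0.36 (permutation p = 0.0405, lower in 5 of 7), as a segment of different copy number that holds both genes would give. Such a segment is known to vary among C57BL/6J mice, and a difference in breeding between the genotypes may thus be a candidate explanation.

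Within 2 Mb of Vegfa 0 of 57 genes passed over the 7 comparisons, Capn11 included, added after its values were seen to those measured in every compartment. In cardiomyocytes at day 3, however, 5 of 60 of these genes had an unadjusted p under 0.05 (Fisher p = 0.00327, the smallest of 7 comparisons, the others 0.0895 to 1), so a passenger segment around the edited locus cannot be excluded.

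In the Q150X heart 2 of day 7, 3 genes chosen after their values were seen stand far above the other 7 hearts (Gbp2 364 CPM, Igtp 319, Cxcl9 89.5), and this heart carries the higher cytokine and interferon medians of that group.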
